A study of Mus musculus with 6 samples.

How the data were processed

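RNA was profiled in 6 cultures of myeloid cells grown from mouse bone marrow. Per the labels' protocols, marrow of C57BL/6 mice aged 2 months was passed through a 40 µm strainer and cultured for 3 days with 40 ng/mL M-CSF, the growth factor of macrophages and their precursors, in medium holding 10% serum. Total RNA was extracted, 4 µg per sample was treated with DNase, and strand-specific total RNA libraries were sequenced on a HiSeq 2500. The labels give 3 libraries as knockout, from mice with floxed PD-L1 alleles and lysozyme-Cre, and 3 as wild type, from littermates with the floxed alleles alone. The design text calls them biological triplicates.

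The submitters' processing notes name FastQC 0.11.2, TopHat2 2.0.12, Picard 1.127, Subread, featureCounts, edgeR and the genome build mm10; their roles and order, the counting options and the annotation are not given in the sources used here. The authors deposited a table of 17382 genes with a TPM value (read counts divided by gene length and scaled to a common total) per library; this unit was read from the values, which are not whole and sum to 1000000 in every library. Per the file headers the same table holds the authors' log2 fold change and mean log2 CPM, a likelihood ratio score, a p-value and an adjusted p-value per gene. In these columns a positive log2 fold change means higher in the libraries labelled knockout, from the values. Gene starts in the table count from 0 and are printed counting from 1; 16352 of the symbols matched RefSeq of the same build, and 99.7% of these lay at an overlapping position. No mitochondrially encoded gene is listed, so that list was not analysed here. Reads of near-identical genes can be shared: among 13690 genes with 30 or more reads in total, 43 had the same 6 read numbers as another gene.

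Depth was recovered from the TPM values. Ratios of a gene's values between libraries are fractions of whole reads, and a search over these fractions gave whole reads, within 0.01 of a read, for 100% of the 94034 values above 0. For 427 genes the common factor was set from the authors' mean log2 CPM. Over 11361 genes with at least 1 CPM, the recovered mean differed from the authors' log2 value by a median of -1.5e-05. In simulated data every read number of a gene was recovered exactly for 99.0% of 2965 genes with a read. The share was 100% for genes with a mean of 5 or more reads. In units of 1000000 reads, the totals were 73.5, 67.9 and 60.6 in the libraries labelled knockout and 52.4, 77.3 and 70.4 in wild type. A library with 0 reads of a gene allows up to 3 reads, which is 0.0388 to 0.0573 CPM; such a floor covers counting error only.

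The planned quasi-likelihood test of edgeR was not run; the deposited unit is TPM, so a test on the log scale is the main one, and limma-voom on the recovered reads is the alternative that models reads. Genotype was tested with limma 3.58.1 in R 4.3.3 (moderated statistics with a mean-variance trend, two-sided, Benjamini-Hochberg adjusted p under 0.05) on log2(TPM + 0.1), for 13722 genes with at least 0.1 TPM in at least 3 libraries. Fold changes are on this scale, which understates the change of low genes, and ± gives the SE of a log2 difference or the SD of 3 libraries. The p-values measure the spread between these 3 and 3 samples; an exact permutation test of 3 against 3 cannot go below 0.1, so none was used. The pseudocount and the filter were set after the values had been seen; other values of both were tried then and are among the alternatives. Tested on simulated reads with 100 genes changed 2-fold and 100 changed 4-fold, the fit recovered 84% and 97% of them among 13587 genes; with the division of the libraries described below added to the simulation it recovered 42% and 85% among 13581 genes. These shares hold for the simulated spread and number of changed genes. In the libraries themselves Iigp1, Gbp2 and Cxcl9, described below, differed by more than 4-fold and did not pass. The shares therefore do not tell how many such changes a count of 0 leaves out.

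Before the data were examined, 32 gene lists were fixed for functions of myeloid cells and for other cell types the culture could hold. The 30 lists with at least 5 measured members were tested with camera (limma, preset correlation 0.01, two-sided, adjusted over the lists), with an estimated correlation and fry as alternatives. Members were also tested adjusted over the list alone. The rule for named genes was also fixed: Cd274 and Lyz2; the 12 genes with the largest log2 fold change each way among those past the threshold, with a mean log2 CPM of at least 1 and no overlap between the groups, or, with fewer than 5 such genes, the 10 with the smallest p under the same requirements, leaving out unnamed genes, small RNAs, pseudogenes and sex-linked genes; up to 4 members of each list with the smallest p; and the 2 most abundant members of lists of other cell types. The rule gives more genes than are named in the text, and the few from outside it are said to be so. Calls near Lyz2 and Cd274 were compared with all other genes by Fisher's exact test in windows of 10 Mb.

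Principal components used log2(TPM + 0.1) of genes with at least 1 TPM in at least 3 libraries. Because the first component divided the libraries across genotype, differences are also given within each side of it and with a term for the side. The sides were read from the values and are not groups of the study, so no gene is given as differing between them; the same division is also 1 of the 10 splits of the libraries for which calls were counted. Other alternatives were scalings, filters, pseudocounts, limma-voom on the recovered reads, a replicate block, robust variance and leaving out libraries. Values were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9.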

Results

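The series compared myeloid cells cultured from marrow of mice whose PD-L1 gene was to be deleted by lysozyme-Cre with cells of floxed littermates, in 3 libraries per group. PD-L1, encoded by Cd274, is the ligand of the inhibitory T cell receptor PD-1. The recovered depth was 52.4 to 77.3 in units of 1000000 reads per library, and 11525 to 11680 genes per library reached 1 TPM.

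Cd274 was not lower in the libraries labelled knockout. The gene lies on chromosome 19 from 29367438 to 29388094 on the plus strand of mm10. Its level was 19.3, 19.2 and 29.2 TPM in the libraries labelled knockout and 17.9, 15.5 and 23.7 TPM in wild type, or 22.6 ± 5.7 against 19.0 ± 4.2 TPM (SD, n = 3 each). The log2 difference of 0.24 ± 0.22 did not pass the limma test (adjusted p = 1.0). Within the negative and the positive side of the first principal component, described below, it was -0.30 and 0.81, and without knockout 3 it was 0.04. The annotation gives the gene 7 exons, the last of which holds 74.7% of the exon length, and the sources used here do not say which exons were floxed. A value for the whole gene therefore does not show whether the floxed exons were lost, and every direction below is drawn from libraries by their labels.

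Lyz2, the lysozyme gene into which the Cre of this kind of line is commonly inserted, lay lower in each library labelled knockout than in any wild-type library. It lies on chromosome 10 from 117277541 to 117282272 on the minus strand. Its level was 19101, 19354 and 13232 TPM in the libraries labelled knockout and 26707, 27493 and 40358 TPM in wild type, a log2 difference of -0.87 ± 0.27, with -1.07 and -1.03 within the negative and positive side. The neighbouring lysozyme gene Lyz1, named after its values were seen, lies from 117287795 to 117292868 and had 131 ± 47 TPM in the libraries labelled knockout and 60.1 ± 15.7 TPM in wild type (SD, n = 3 each), a log2 difference of 1.09 ± 0.30. Neither gene passed the limma test over all genes. In the authors' deposited table both are called, with adjusted p-values of 0.0345 for Lyz2 and 0.00602 for Lyz1, and they are the 2 called genes among 110 within 10 Mb of Lyz2 (Fisher's exact test, two-sided, p = 0.0343 against all other genes). Lyz2 itself anchors this window, and without it 1 of 109 genes is called (Fisher's exact test, p = 0.247). With windows of 5 and 20 Mb the p was 0.0107 and 0.103 with Lyz2, and 0.140 and 0.414 without it. The authors' calls were used because limma made none near either gene. No gene within 10 Mb of Cd274 is called in the authors' deposited table.

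**Figure D1:**
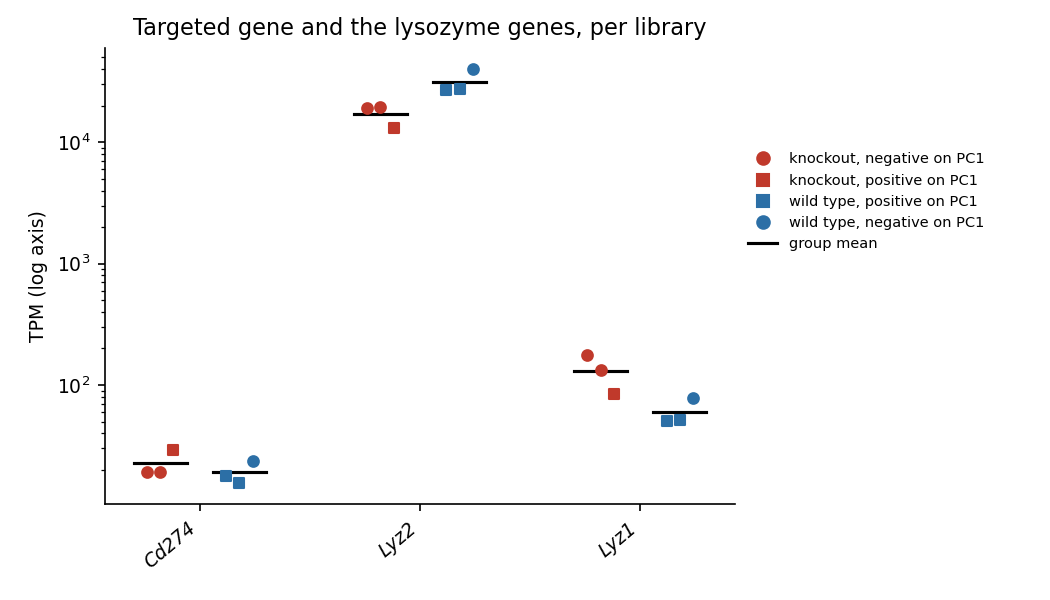
TPM on a log axis of Cd274, Lyz2 and Lyz1 in each of the 6 libraries, with bars at group means. Circles and squares mark the negative and positive side of the first principal component. Cd274 of the libraries labelled knockout spans 19.2 to 29.2 TPM and overlaps wild type, while their Lyz2 values of 13232 to 19354 TPM lie below all wild-type values.

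The libraries did not divide by genotype along the component that held most of the variance. The first principal component held 54.7% of the variance and set knockout 1 and 2 and wild type 3 (-19.8, -15.3 and -26.2) apart from knockout 3 and wild type 1 and 2 (26.3, 17.0 and 18.1). Knockout 1 correlated more closely with wild type 3 (Pearson r across genes of 0.993) than with knockout 3 (0.976); genes are not independent replicates. Among the genes with the highest loadings on the positive side were the chemokine genes Ccl7 and Ccl2, the urokinase gene Plau and the cyclin gene Ccnd1, and among those on the negative side was the apolipoprotein gene Apoe, all named after their values were seen. Plau had 235 and 228 TPM in knockout 1 and 2 and 159 TPM in wild type 3, against 1000 TPM in knockout 3 and 607 and 653 TPM in wild type 1 and 2. Apoe had 4066, 2945 and 4842 TPM in the libraries of the negative side and 581, 1065 and 1206 TPM in those of the positive side. The sides were read from the values, so these are levels and not a test.

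**Figure D2:**
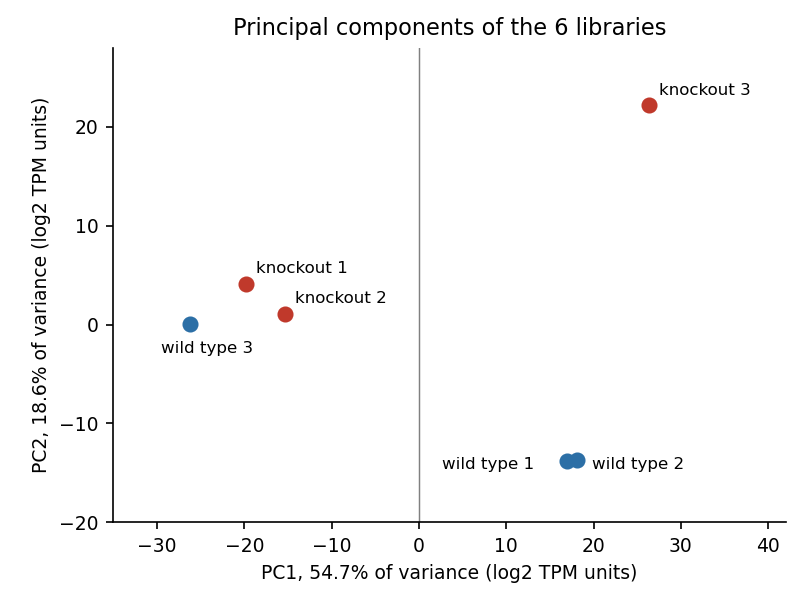
The 6 libraries on the first and second principal components of log2(TPM + 0.1), in log2 units, with red for libraries labelled knockout and blue for wild type. The first component, with 54.7% of the variance, places wild type 3 beside knockout 1 and 2, and knockout 3 with wild type 1 and 2.

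In the test of genotype, 0 genes were higher and 0 lower at an adjusted p under 0.05 (limma), among 13722 genes. At an unadjusted p under 0.05 there were 299 genes, or 2.18%, and the groups did not overlap for 702 genes, or 5.12%, where chance gives 10%. That 10% is a mean over all splits of the libraries into 3 and 3. The split along the first component gave 47.3%, and the other splits that mix the labels gave 3.87% to 10.2%. limma-voom on the recovered reads also called 0 genes, with 310 at an unadjusted p under 0.05. Without wild type 3 the number at an unadjusted p under 0.05 was 1012, with 0 calls. Without knockout 3 and wild type 3, left out after their places on the first component had been seen, 738 genes were higher and 758 lower, but genotype and side then coincide. The authors' deposited table calls 46 genes, 42 higher and 4 lower in the libraries labelled knockout; 44 of the 46 were tested with limma and all 44 had the same sign there. Of the called genes in the authors' deposited table, 8 belong to the interferon gamma list below, 6 to the T and NK cell list, and 22 had a mean under 1 TPM.

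Of the 10 genes with the smallest p that the rule names, 9 were higher in the libraries labelled knockout, and 4 of these, Iigp1, Gbp2, Gbp6 and Irf1, belong to the interferon gamma list. Iigp1, an interferon-inducible GTPase, had 56.0 ± 42.5 TPM there and 4.13 ± 2.47 TPM in wild type (SD, n = 3 each), a log2 difference of 3.61 ± 0.60. Gbp2, a guanylate-binding protein, had 66.9 ± 26.2 and 12.3 ± 7.5 TPM, a log2 difference of 2.52 ± 0.46. Gbp6 of the same family, the GTPase gene Tgtp2, the serpin gene Serpina3g and the receptor gene Slamf8 differed by 2.46 ± 0.48, 2.00 ± 0.46, 2.59 ± 0.44 and 1.53 ± 0.33 on the log2 scale. Irf1, a transcription factor of the interferon response, had 74.4 ± 7.0 against 39.5 ± 12.5 TPM. AW112010 and the phospholipase gene Pla2g16 were also higher, by 1.35 ± 0.24 and 0.69 ± 0.13. The integrin gene Itgad was the exception, with 0.82 ± 0.25 against 2.04 ± 0.29 TPM. The groups did not overlap for any of these 10 genes, which the rule required. None passed the limma test over all genes, where the smallest adjusted p of any gene was 0.341. In the authors' deposited table all but Pla2g16 are called, with adjusted p-values from 3.7e-10 (Iigp1) to 0.0194 (Itgad). Of the genes named further below, that table also calls Cxcl9, Cd8a, Cd3e, Gzmb, Il2rb, Ccl5, Pdcd1 and Vsig4, and not the others.

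Genes of the interferon gamma response and antigen presentation lay higher as a group. All 36 measured members had a positive log2 difference, with a median of 0.51; 0 passed over all genes and 19 rose when adjusted over the list alone, with 0 falling. With the term for the side of the first component 13 rose and 1 fell over the list alone; the latter, the receptor gene Ifngr1, named after its values were seen, had a log2 difference of -0.17 ± 0.05 in that fit. For 21 of the 36 the groups did not overlap, where chance gives 10% per gene and the share over all tested genes was 5.12%. The members move together (estimated correlation 0.42), so they are not separate draws. Cxcl9, a chemokine that attracts activated T cells, had 3.16 ± 1.66 against 0.129 ± 0.051 TPM, a log2 difference of 3.72 ± 0.42. The list's mean log2 value was higher by 0.84 ± 0.23 (SE), by 0.38 within the negative side of the first component and 1.2 within the positive side, and lay higher in each library labelled knockout than in any of wild type. The camera test gave an adjusted p of 2.1e-36 with the preset correlation, and an adjusted p of 0.19 with an estimated correlation. Of the 30 lists tested, 14 passed with the preset correlation, and 0 with an estimated correlation or with fry.

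**Figure D3:**
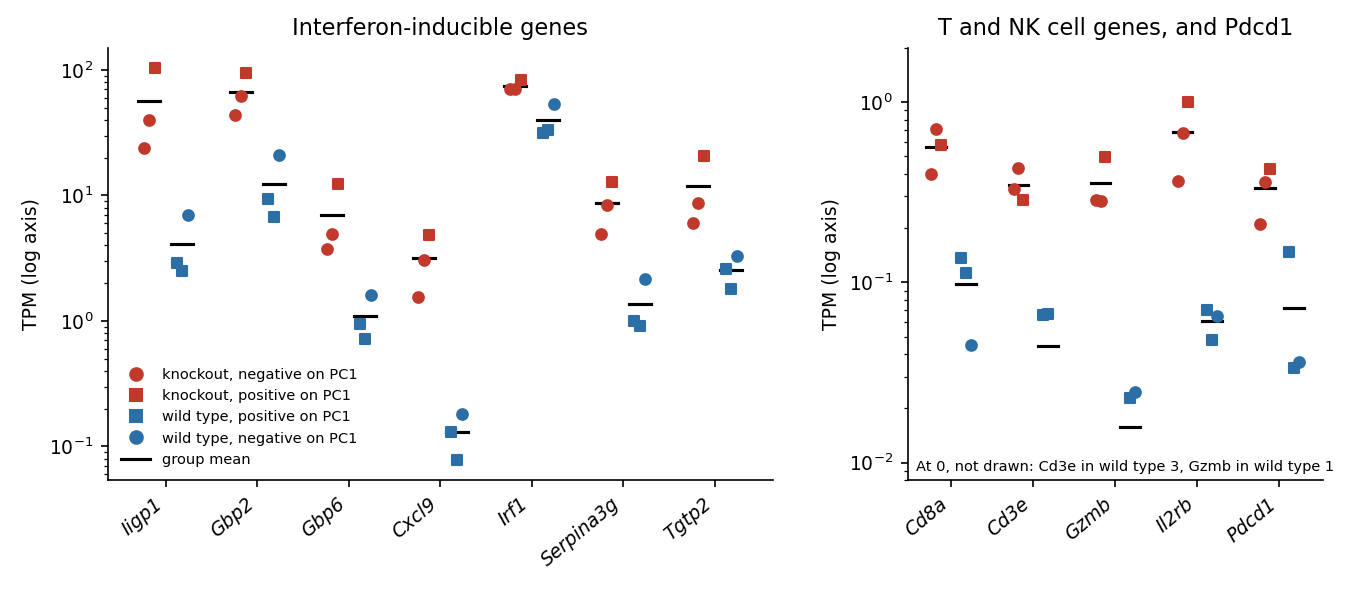
TPM on a log axis of 7 interferon-inducible genes, 4 genes of T and NK cells and Pdcd1 in each library, with bars at group means, and with circles and squares for the negative and positive side of the first principal component. For these chosen genes every point of the libraries labelled knockout lies above every wild-type point of the same gene, for example 1.56 to 4.88 TPM against 0.0775 to 0.180 TPM for Cxcl9.

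Genes of T and NK cells were also higher in the libraries labelled knockout, at low levels. Of 15 measured members 14 had a positive log2 difference. Over all genes 0 passed, and 10 rose when adjusted over the list alone. For 10 the groups did not overlap, where chance gives 10% per gene. The members can move together (estimated correlation 0.18), so they are not separate draws. With the term for the side 12 rose over the list alone and 1, Cd4, fell. None of the 15 is in another list. Cd8a, a coreceptor of cytotoxic T cells, had 37, 61 and 44 reads in these libraries and 9, 11 and 4 reads in wild type. Cd3e, a part of the T cell receptor complex, had 14, 17 and 10 against 2, 3 and 0 reads, and Gzmb, a protease of cytotoxic granules, 12, 11 and 17 against 0, 1 and 1 reads. The interleukin receptor gene Il2rb had 0.683 ± 0.323 against 0.061 ± 0.012 TPM. Il2rb, Cd3e and Gzmb reached the filter's 0.1 TPM only in the libraries labelled knockout. Such members were measured because they were high there, so the counts and the test of this list are partly set by the filter. The most abundant members, Il7r and Cd4, which cultured myeloid cells can also express, had 81.3 ± 35.3 against 69.3 ± 17.5 TPM and 14.2 ± 8.6 against 13.5 ± 10.3 TPM. The list's mean differed by 1.08 ± 0.18, by 0.98 and 1.24 within the negative and positive side (camera adjusted p = 6.1e-21, and adjusted p = 0.16 with an estimated correlation). With the filter of 1 TPM too few members were left to test the list.

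The type I interferon list had 40 of 42 members with a positive log2 difference and 0 that passed, over all genes or over the list alone. Its mean differed by 0.38 ± 0.30, but the difference was -0.17 within the negative side and 0.93 within the positive side (camera adjusted p = 3.4e-15, and adjusted p = 0.39 with an estimated correlation). Ifi44 had 7.80 ± 4.05 against 3.19 ± 1.69 TPM. Zbp1 and Ifit2 differed by 1.11 ± 0.44 and 0.95 ± 0.42 on the log2 scale, with overlapping groups; without wild type 2 these differences were 0.71 and 0.60, and that of Ifi44 was 0.84 in place of 1.3.

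Among chemokines and their receptors 1 of 28 members, Cxcl9, rose when adjusted over the list alone. Ccl5 had 8.61 ± 1.74 against 2.46 ± 1.62 TPM, and Ccr3, the eotaxin receptor, 5.32 ± 0.90 against 9.19 ± 1.51 TPM; camera gave an adjusted p of 0.018, and an adjusted p of 0.31 with an estimated correlation. For inflammatory cytokines and for immune checkpoint and costimulation genes, adjusted p-values were 0.0073 and 0.0053, and both had an adjusted p of 0.27 with an estimated correlation. Il12a, a subunit of interleukin 12, had 1.45 ± 0.03 against 2.12 ± 0.05 TPM, and Il27 2.80 ± 0.67 against 1.46 ± 0.43 TPM. Pdcd1, which encodes PD-1, had 12, 19 and 20 reads in the libraries labelled knockout and 6, 2 and 2 in wild type. The calls of the chemokine, cytokine and checkpoint lists ended without knockout 3 (adjusted p = 0.099, 0.16 and 0.20) and without wild type 2 (0.29, 0.29 and 0.054), that of chemokines also without wild type 3 (0.13) and that of cytokines also without knockout 1 (0.090). The checkpoint call also ended with the filter of 1 TPM (0.058), and all 3 ended without both knockout 3 and wild type 3 (0.35, 0.085 and 0.31). Over the 6 left-out libraries the lowest adjusted p-values were 0.00018, 0.0032 and 0.00036. With the term for the side 3 chemokine genes rose and 1, Ccr3, fell over the list alone, and 2 checkpoint genes rose.

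Lists of B and plasma cells, erythroid cells, megakaryocytes and stroma lay lower in the libraries labelled knockout. All 15 measured members of the B and plasma cell list and all 15 of the erythroid list had a negative log2 difference, as did 12 of 14 megakaryocyte and 14 of 17 stromal members; none of these members passed, over all genes or over the list alone. With the term for the side of the first component, 4 megakaryocyte members fell over the list alone and no member of the other 3 lists passed. The list means differed by -0.51 ± 0.25, -0.35 ± 0.12, -0.30 ± 0.18 and -0.34 ± 0.15, and those of the erythroid list alone did not overlap between the groups. Vpreb3, a B cell precursor gene, had 5.44 ± 1.39 against 9.45 ± 2.19 TPM, and the most abundant B cell gene, Cd79b, 33.6 ± 8.2 against 44.9 ± 3.5 TPM. Among abundant members of the other 3 lists, the globin gene Hbb-bs had 25.5 ± 8.7 against 42.2 ± 18.8 TPM, the platelet factor gene Pf4 908 ± 181 against 889 ± 29 TPM, and Spp1, which macrophages also express, 3040 ± 1747 against 2420 ± 656 TPM. With single libraries left out the log2 difference ranged from -0.61 to -0.26 for Cd79b and from -0.95 to -0.35 for Hbb-bs, and those of Pf4 and Spp1 changed sign. Camera adjusted p-values were 3.4e-15, 1.2e-07, 1.7e-09 and 2.4e-05, and the adjusted p-values with an estimated correlation were 0.27, 0.19, 0.31 and 0.27. Without wild type 3 the stromal call ended, with an adjusted p of 0.13 (range over the 6 left-out libraries 3.8e-10 to 0.13), as it did with the filter of 1 TPM (0.32). Without both knockout 3 and wild type 3 the calls of all 4 lists ended, with adjusted p-values of 0.065, 0.10, 0.57 and 0.10.

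Osteoclast genes did not pass the test as a list. Of 29 measured members 14 had a positive and 15 a negative log2 difference, 0 passed, the list mean differed by -0.01 ± 0.12, and camera gave an adjusted p of 0.85 (0.029 without wild type 2). Car2, the carbonic anhydrase of osteoclasts, had 1.64 ± 0.22 against 2.45 ± 0.45 TPM. The negative regulators of osteoclast formation had an adjusted p of 0.27, with Bach2 at 2.34 ± 0.33 against 3.60 ± 0.55 TPM. Macrophage identity genes gave an adjusted p of 0.32 (0.0077 without wild type 1), with a median log2 difference of 0.01 and a mean of -0.10, and 0 of 31 members passed, while 3 fell over the list alone with the term for the side; Vsig4 and Timd4, receptors of resident macrophages, had 0.944 ± 0.125 against 2.79 ± 1.23 TPM and 0.741 ± 0.167 against 1.65 ± 0.61 TPM. Monocyte and alternative activation genes gave adjusted p-values of 0.57 and 0.69, and without wild type 2 that of monocytes was 0.0021. With the term for the side of the first component the osteoclast and macrophage lists passed (adjusted p = 0.024 and 0.00695), and with an estimated correlation as well they did not (adjusted p = 0.50 and 0.39).

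Cholesterol synthesis genes were higher by little: all 23 measured members had a positive log2 difference, the list mean differed by 0.11 ± 0.07, and camera gave an adjusted p of 2.5e-06, and an adjusted p of 0.31 with an estimated correlation; without both knockout 3 and wild type 3 the call ended (0.35). Cell cycle genes had 41 of 45 members with a negative log2 difference, but the list mean differed by 0.21 within the negative side and -0.22 within the positive side; the camera adjusted p was 2.1e-05, the adjusted p with an estimated correlation 0.72, and the call ended without wild type 2 (0.30) and with the term for the side (0.51). The integrated stress and hypoxia lists gave adjusted p-values of 0.015 and 0.044, adjusted p-values of 0.79 and 0.72 with an estimated correlation, 0.12 and 0.20 without knockout 3, where the direction reversed, and 0.69 and 0.40 without wild type 3. Both kept their direction and passed with the term for the side (adjusted p = 6.1e-09 and 7.8e-07), and with an estimated correlation as well each had an adjusted p of 0.39. Without both knockout 3 and wild type 3 the direction of both was reversed, and integrated stress passed in that direction (adjusted p = 0.018), while hypoxia did not (0.10). No member of these 4 lists passed, with or without the term for the side. Lists that did not pass were phagocytosis and lysosome (adjusted p = 0.27), replication-dependent histones (0.071), glycolysis (0.28), oxidative phosphorylation (0.59), cytosolic ribosomal proteins (0.49), heat shock (0.32), immediate early genes (0.21), neutrophils and granulocyte precursors (0.89), mast cells, basophils and eosinophils (0.61), dendritic cells (0.42), and stem and progenitor cells (0.19, with a list mean of 0.03 but a median of -0.10). Each of these 11 lists passed when some single library was left out, with lowest adjusted p-values from 1.3e-08 for neutrophils without wild type 2 to 0.029 for oxidative phosphorylation without wild type 2. With the term for the side glycolysis, dendritic cell and heat shock genes passed (adjusted p = 1.2e-07, 0.031 and 0.045, the last with the direction reversed), and with an estimated correlation as well each had an adjusted p of 0.39; 2 histone genes rose over the list alone with this term. Without both knockout 3 and wild type 3 glycolysis, in the reverse direction, lysosome and heat shock genes passed (0.0012, 0.0023 and 0.00057). Of the sex-linked list only Xist was measured, with 181 ± 8 against 195 ± 23 TPM.

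**Figure D4:**
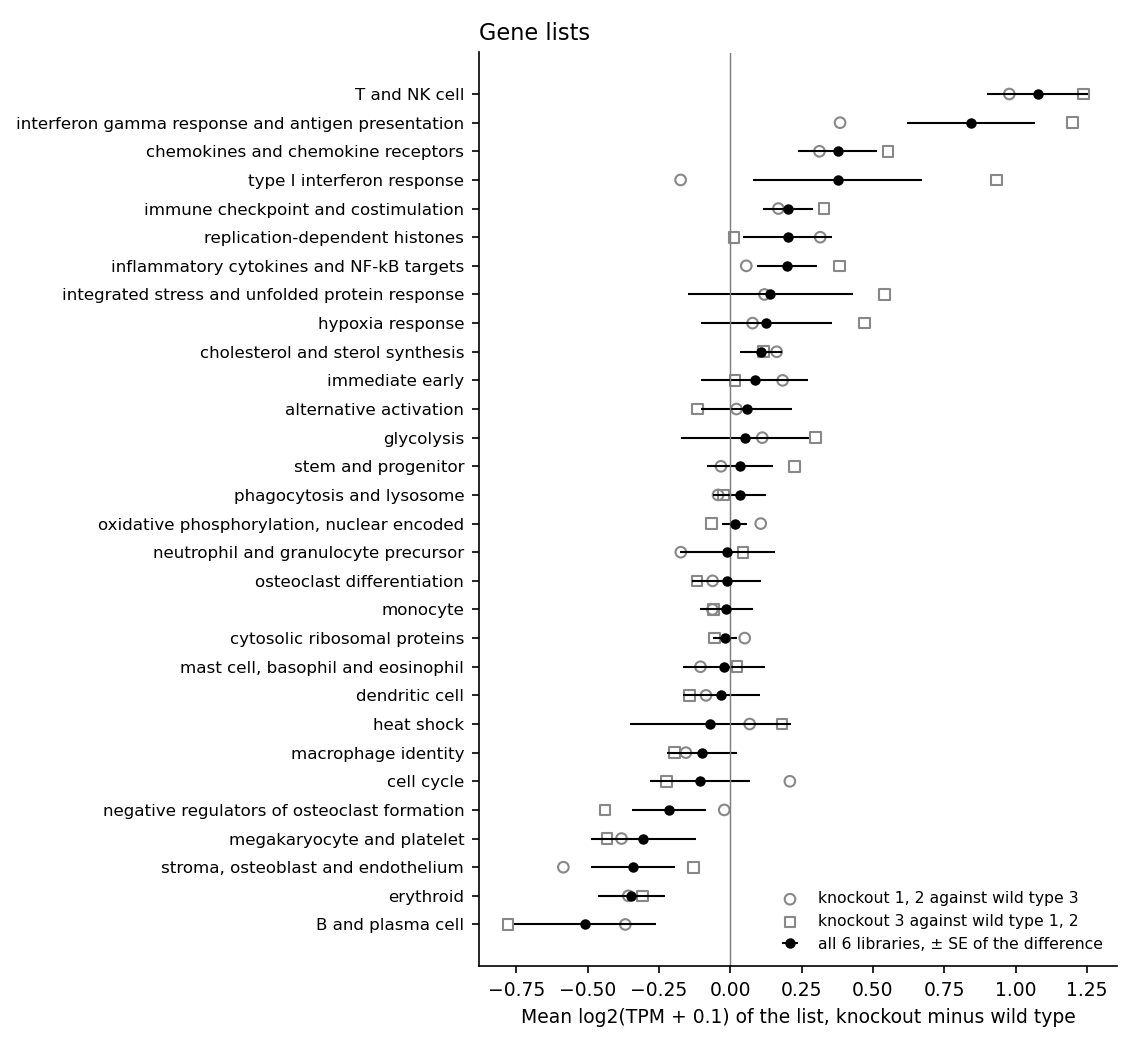
Difference of the mean log2(TPM + 0.1) of each of the 30 lists, libraries labelled knockout minus wild type. Black points are all 6 libraries with the SE of the difference, open circles knockout 1 and 2 against wild type 3, and open squares knockout 3 against wild type 1 and 2. The T and NK cell list at 1.08 and the interferon gamma list at 0.84 are the highest, and the type I interferon list has opposite signs on the 2 sides.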

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

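Alternatives chosen after seeing the data were the pseudocounts, the filters of 0.1 TPM in 1 library and of 1 TPM joined with a pseudocount of 0.5 TPM, robust variance, the principal component term, limma-voom with either of these, leaving out both knockout 3 and wild type 3, and the authors' calls near the loci, with and without Lyz2 itself. The planned edgeR and DESeq2 tests were not run; limma-voom on the recovered reads was the test that models reads, and their median-of-ratios and upper-quartile scalings were applied to TPM and moved the median of all genes by under 0.1. The limma count of 0 genes higher and 0 lower held under the other alternatives, the stricter thresholds and each left-out library (0 to 0 genes), with 168 to 1042 genes at an unadjusted p under 0.05. limma-voom with the principal component term called 1 gene lower (Lyz2), and with robust variance as well 1 higher (Plau) and 1 lower (Lyz2). Without knockout 3 and wild type 3 limma called 738 genes higher and 758 lower; in the 4 libraries left, genotype and the side of the first component coincide. Cd274 had a positive log2 difference and missed the threshold in all settings, from 0.04 to 0.41 (adjusted p 0.218 to 1.0). The number of lists past the threshold was 12 to 18 with single libraries left out and 8 without knockout 3 and wild type 3; it was 0 with an estimated correlation, 0 with fry, and 0 with the principal component term and an estimated correlation. Near Lyz2 the p of the authors' calls was 0.103 in a window of 20 Mb, which holds 206 genes, and 0.247 in 10 Mb without Lyz2 itself, which leaves 1 call. Of 958 pairs of a named gene and a setting, 926 had the sign given in the results; most of these genes were picked by their smallest p. Leaving out 1 library moved the log2 difference of 13 of the 41 named genes by over 1.5 times: Cd274, Ifi44, Zbp1, Ifit2, Il7r, Cd4, Cd79b, Hbb-bs, Pf4, Spp1, Xist, Plau and Ifngr1. Gzmb, Il2rb and Cd3e fall below some filters and have no value there. With at least 1 TPM in 3 libraries the T and NK cell and histone lists kept fewer than 5 members and were not tested.

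List directions reversed as follows, with adjusted p-values in brackets; the cause was not tested. Without knockout 3 and wild type 3 these were osteoclast (0.0618), macrophage (0.153), monocyte (0.351), glycolysis (0.00115), hypoxia (0.105), integrated stress (0.0175), neutrophil (0.177), mast cell (0.900) and dendritic cell (0.314) genes. With the principal component term they were alternative activation (0.236), lysosome (0.232) and heat shock (0.0453), and with an estimated correlation as well 0.509, 0.509 and 0.388. With at least 1 TPM they were alternative activation (0.622) and neutrophil (0.953), and with fry neutrophil (0.968). With single libraries left out the direction reversed at least once for lists whose adjusted p-values ranged from 0.0288 to 0.820 (osteoclast), 0.00769 to 0.840 (macrophage), 0.00212 to 0.946 (monocyte), 0.0761 to 0.827 (alternative activation), 0.00628 to 0.955 (lysosome), 0.00476 to 0.683 (glycolysis), 0.000117 to 0.400 (hypoxia), 0.0288 to 0.955 (oxidative phosphorylation), 0.0173 to 0.702 (ribosomal), 2.72e-05 to 0.689 (integrated stress), 0.00154 to 0.933 (heat shock), 1.68e-05 to 0.783 (immediate early), 1.29e-08 to 0.930 (neutrophil), 0.00101 to 0.688 (mast cell) and 0.0162 to 0.840 (dendritic cell). Log2 differences of genes that crossed 0 with single libraries left out were -0.15 to 0.37 for Il7r, -0.34 to 0.71 for Cd4, -0.094 to 0.19 for Pf4, -0.22 to 0.47 for Spp1, -0.78 to 0.29 for Plau and -0.084 to 0.27 for Ifngr1. Without knockout 3 and wild type 3, Il7r was at -0.36 and Spp1 at -0.42. With the principal component term Cd4, Pf4, Plau and Ifngr1 were at -0.49, -0.088, 0.61 and -0.17, and with limma-voom and the term, with or without robust variance, at -0.50, -0.094, 0.60 and -0.18.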

Other observations

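Most tests in this part were chosen after the result they measure had been seen; the test on the exons of Cd274 was fixed beforehand. For 2 tests on the interferon gamma list the rule written first was later replaced. For the division along the first component, a limit of 2 SE, under which the value printed below argues against that division, gave way after the value had been seen to a 95% interval that allows for the few libraries. For the graded response, a correlation over the 3 libraries labelled knockout, too few for one, gave way to a slope over all 6. Under the rules first written for T cell RNA read directly and for library size, the values printed below argue against both. The rule for library size was set aside as well, for the reason given there. For T cell RNA the reading was narrowed to the whole source. Interferon gamma itself was near the limit of detection: Ifng, named after its values were seen, had 5, 8 and 9 reads in the libraries labelled knockout and 4, 4 and 3 reads in wild type. In TPM these were 0.140, 0.242 and 0.307 against 0.156, 0.107 and 0.0868, so the groups overlapped. Without Il7r and Cd4, which were set aside after their values were seen, the reads of the T and NK cell list were 8.26 ± 2.00 CPM in the libraries labelled knockout and 3.99 ± 0.55 CPM in wild type (SD, n = 3 each).

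The real grouping called 0 genes, and the highest of the other 9 splits of the 6 libraries into 3 and 3 called 3953. A comparison with a count of 0 decides nothing. The split with 3953 genes sets knockout 1 and 2 and wild type 3 against the rest, which is the division along the first component read from the same values, so its count restates that structure of the libraries and is no further evidence of it. For gene lists the real grouping gave 14 past the threshold and the highest other split 16, with 7 of 10 splits giving 14 or more. With 10 splits a share under 0.05 cannot be reached.

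The interferon gamma list was higher in the libraries labelled knockout. Its mean differed by 0.84 ± 0.23 (SE), and by 0.792 ± 0.261 (SE) with a term for the division along the first component. The term thus took away little of the estimate. With 3 residual degrees of freedom the 95% interval of -0.04 to 1.62 includes 0, so that division is not excluded as the whole cause. RNA of T cells read directly is argued against as the whole source. The interferon gamma list was higher by a summed 2012 TPM and the T and NK cell list by 18.6 TPM. The latter is 0.925% of the former, or 0.289% without Il7r and Cd4. As the whole source, T cells would have to hold RNA of both lists in that ratio. T cells also carry genes of the interferon gamma list, in a ratio not measured here, so a part from them stays open. For an interferon response of the myeloid cells to a few T or NK cells, graded with their number, the slope of the interferon gamma list mean on the T and NK cell list mean, with a term for genotype, was 0.673 ± 0.622 (95% interval -1.31 to 2.65), which does not decide it. Such a response may account for both lists, with Il7r and Cd4, the most abundant members and ones myeloid cells can express, at 81.3 against 69.3 and 14.2 against 13.5 TPM; no sort of the cells is named in the labels, and an effect of genotype on the myeloid cells themselves stays open.

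Cd274 was not lower in the libraries labelled knockout, while Lyz2 was lower in each of them. An exchange of the labels of knockout 3 and wild type 3, whose places on the first component are crossed, is argued against by Lyz2, which was 3.05 times as high in wild type 3 as in knockout 3. Reads from the part of the gene outside the deleted exons could hide a deletion: the last exon alone holds 74.7% of the exon length, and reads per exon were not analysed here. Deletion in only some of the cells also stays open and was not tested.

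The division along the first component was set against library size, sequence composition and growth factor state. In units of 1000000 reads the totals were 67.9 to 73.5 on the negative side and 52.4, 60.6 and 77.3 on the positive side; wild type 2 alone makes them overlap, so library size stays open. Across genes, the larger Spearman correlation of the loadings with GC content or exon length was 0.112 in size, which argues against sequence composition. For the state of growth factor signalling, a list of MAPK output genes had a median loading at percentile 100 of 10000 random lists, and a list of growth factor withdrawal genes at percentile 0; both lists were drawn up after the leading genes of the component had been seen, and 1 member, Fosl1, was among those, so they cannot decide it. A difference in handling or day, which the labels do not give, also stays open.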
